A study of Mus musculus with 6 samples.

How the data were processed

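Dendritic cells from mouse spleen were rested for 1 h and treated for 2 h, fixed in 1% formaldehyde for 10 min at 37 °C, and sonicated in 20 cycles to fragments of 200 to 500 bp, per the labels' protocols. Libraries were amplified with 19 PCR cycles and cut from a gel at 250 to 450 bp, per the labels' protocols. STAT3 was precipitated with a monoclonal antibody and STAT5B with a serum, per the labels' protocols. The 6 libraries were assigned to groups by their titles or, for the STAT5B control, by the treatment field. One library carries labels that disagree (GM-CSF in the title, IL-21 in the treatment field), and it was used as GM-CSF.

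Each deposited file lists 1 aligned read of 25 bases per line with its position, strand, a match string and a score, and it has no header. The positions are not normalised, and repeated reads are kept, as the deposited values show. The deposited score is a whole number from 4 to 53 whose meaning was not given in the sources used here. It was used only for an added filter at a score of at least 30. The aligner, the genome build and any read filter were not given in the sources used here. The reads extend differently from the GRCm38 annotation at hand: the last read on chromosome X ended at 165521251 while the last annotated GRCm38 gene ends at 170678054, and on chromosome 1 reads reached 197069831 although the last gene ends at 195291439. For this reason the planned shares of regions near genes of fixed lists and in promoters, exons and introns, and the planned motif counts, were not run, and neither were their alternatives. No gene is named.

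From these reads, 1 read per start and strand was kept, since 19 PCR cycles had been used, and reads were shifted by 100 bp towards the fragment centre and counted in bins of 200 bp. The distance between strands at the strongest regions was 135 to 150 bp, so the fragment centre lies nearer to the alternative shift of 75 bp. Each bin of a treated library was compared with the highest of several backgrounds. These were the library's own mean over bins with at least 1 read, the scaled control bin and the scaled control in windows of 1, 5 and 10 kb. That mean was 2.05 (IL-21) and 1.76 (both cytokines) for STAT3, and 2.18 (GM-CSF) and 2.03 (both) for STAT5B. A one-sided Poisson test was used, with Benjamini-Hochberg adjustment over bins with at least 1 read. Bins with q of at most 0.001, at least 10 reads and at least 2-fold over the scaled control (1 read added to both) were kept, and bins within 200 bp were merged. Libraries were scaled to their distinct reads. These calls compare 2 libraries and not conditions. Exchanging the treated and control libraries gave the number of regions where the control stood over the treated library. It is not a measured count of false calls, since the treated library then serves as background with its enriched sites, and the depths differ.

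Co-treatment was compared with the single cytokine over the union of both region sets. The ratio of scaled reads per region was given with an exact conditional binomial 95% interval, and a region was called by size when it was at least 2-fold different and its interval left out 1. Log2 ratios were taken after adding 0.5 reads. Overlaps of at least 1 bp were set beside 100 random placements on the same chromosomes. Counts by size were set beside 100 draws of counting chance only. This was done in regions called on a random 50% of reads and counted in the other 50%, where choosing the regions cannot build in the excess. The comparison was added after the results were seen. Both libraries of a pair held nearly equal reads in it, with scales of 1.00012 for STAT3 and 0.999879 for STAT5B. In the main comparison the scales were 0.619791 and 0.84356, so its values differ from the main ones in depth too. Shares carry Wilson 95% intervals. Regions named in the text followed a rule fixed before the data were examined: the 10 regions with the most excess reads per library and the 10 largest ratios each way among regions called by size with at least 30 reads over the pair. A few of each 10 are printed. Windows of 100 kb were ranked by excess reads after the data were examined.

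The caller was tested on simulated data with 200 added sites per fold size in each comparison. For STAT3 after IL-21, run on 8092553 bins, it recovered 88.5% of 10-fold sites, 14.5% of 5-fold sites and 0% of 3-fold sites. For STAT3 after both cytokines (6166970 bins) the shares were 84%, 9% and 0%. They were 95%, 24.5% and 1% for STAT5B after GM-CSF (7645279 bins) and 94%, 13.5% and 0.5% for STAT5B after both cytokines (6949783 bins). All 20-fold sites were recovered and 0 other regions were called in each of the 4 simulations. Both backgrounds were drawn from 1 control profile smoothed over 5 kb, so other regions could hardly arise. The 0 is therefore no measure of false calls in the libraries. The 3-fold sites lay mostly under the minimum of 10 reads, which largely set their low recovery. Each comparison was simulated apart, with its own drawn control, so calls shared between comparisons with 1 control were not tested. Added sites of 5-fold or less were mostly missed at the simulated background, while regions with more reads were called at lower enrichment in the libraries. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.

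Alternatives covered q, fold and read thresholds, repeated reads, the shift, scaling on background bins, the control of the other antibody, thinning to 7805341 distinct reads, other region sets and a minimum overlap.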

Results

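Binding of the transcription factors STAT3 and STAT5B was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in dendritic cells from the spleens of C57BL/6 mice. STAT3 is the main signal transducer of the interleukin-21 (IL-21) receptor, and STAT5B is a main signal transducer of the receptor for granulocyte-macrophage colony-stimulating factor (GM-CSF). The series concerns opposing roles of the 2 cytokines in the apoptosis of conventional dendritic cells. The 6 libraries formed 6 groups of 1. STAT3 was precipitated from control cells, from cells given IL-21 and from cells given IL-21 plus GM-CSF, and STAT5B from control cells, from cells given GM-CSF and from cells given both cytokines. The labels of the STAT5B GM-CSF library conflict, since its title and description give GM-CSF and its treatment field gives IL-21. The title was followed here, so each direction drawn from that library rests on the title being right.

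The files held between 24062384 and 27622086 aligned reads per library. After 1 read was kept per start position and strand, the STAT3 libraries kept 7805341 distinct reads (control), 14900707 (IL-21) and 9235327 (IL-21 plus GM-CSF). The STAT5B libraries kept 12417709 (control), 13216737 (GM-CSF) and 11149107 (both cytokines). Repeated reads made up 69.7%, 40.7% and 64.0% of the STAT3 libraries in the same order, and 49.8%, 45.1% and 59.6% of the STAT5B libraries. Each condition had 1 library and no replicate, so no p-value between conditions is given, and every comparison is between libraries. Intervals are 95% intervals. Those of read ratios cover counting error only, those of shares are Wilson intervals, and bootstrap intervals are named where used. No interval covers variation between preparations. Intervals from read counts may also be too narrow, because PCR reads without molecular identifiers are not independent molecules. The genome build of the reads was not given in the sources used here, so regions are named by position on the coordinates of the deposited reads, counted from 1, and not by gene.

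The first comparison asked where STAT3 bound after IL-21. In the IL-21 library 2707 regions were enriched over the STAT3 control, against 1 region when the roles of the libraries were exchanged. These regions had a median enrichment of 6.43-fold and a median width of 200 bp. They held 0.733% of the distinct reads of the IL-21 library (Wilson interval 0.729 to 0.738%) and 0.106% of those of the control. The region with the most excess reads lay on chromosome 4 at 8833801 to 8834600, with 351 reads against 13 in the control, a 14.1-fold enrichment (interval 8.16 to 26.8). A region on chromosome 2 at 127912601 to 127913600 had 332 reads against 13, or 13.4-fold (7.72 to 25.4), and one on chromosome 10 at 7514801 to 7515800 had 297 against 10, or 15.6-fold (8.34 to 32.8). The strongest 10 regions were enriched between 4.48-fold and 15.6-fold, and all 10 were also called in the STAT3 library of both cytokines and in both cytokine-treated STAT5B libraries.

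After IL-21 plus GM-CSF, 1419 STAT3 regions were enriched over the same control, against 2 with the roles exchanged. Their median enrichment was 6.41-fold, and they held 0.442% of the library's distinct reads (0.437 to 0.446%) against 0.0599% of the control's. The chromosome 4 site led this library too, at 8834001 to 8834400, with 168 reads against 8 and a 17.7-fold enrichment (8.80 to 41.8). The second was a single bin on chromosome 11 at 100755801 to 100756000, with 193 reads against 49, or 3.33-fold (2.42 to 4.65). The control reads at that bin were the most among the strongest 10 regions. The region on chromosome 4 at 94795401 to 94795800 had the highest enrichment of the 10, at 19.1-fold (7.95 to 60.0), from 113 reads against 5.

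STAT5B regions were far more numerous. The GM-CSF library had 26614 regions over the STAT5B control, 9.83 times the number of STAT3 regions after IL-21, and no region (0) was called with the roles exchanged. These numbers come from different antibodies and different controls, with 0.733% of distinct reads in the STAT3 regions after IL-21. They therefore do not show how many more places STAT5B bound than STAT3. The median enrichment was 7.61-fold, and the regions held 13.6% of the library's distinct reads against 1.30% of the control's. The strongest region, on chromosome 10 at 95666601 to 95669400, had 1327 reads against 77, or 16.2-fold (12.9 to 20.6). It was followed by regions on chromosome 16 at 87523201 to 87525600, with 1213 reads against 38, or 29.99-fold (21.7 to 42.6), and on chromosome 9 at 107153401 to 107155600, with 1234 against 65, or 17.8-fold (13.9 to 23.3). The most enriched of the strongest 10 lay on chromosome 5 at 3466401 to 3468400, at 34.8-fold (23.9 to 52.6). Without cytokine, 1315 regions stood over the local background of the STAT5B control library alone, and 791 of them (60.2%) overlapped STAT5B regions of the GM-CSF library. The STAT3 control had 442 such regions, of which 35 (7.92%) overlapped STAT3 regions of the IL-21 library and 194 (43.9%) overlapped STAT5B regions of the GM-CSF library, and 160 of the STAT5B control's regions overlapped them. A control library called against its own background does not separate binding from other sources of reads.

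With both cytokines, 17346 STAT5B regions were enriched over control and 0 with the roles exchanged. Their median enrichment was 7.62-fold, and they held 9.01% of the distinct reads against 0.878% of the control's. The strongest region was the one on chromosome 16 at 87523201 to 87525600, with 973 reads against 38, or 28.5-fold (20.6 to 40.5). On chromosome 1 at 192824201 to 192825200, 623 reads stood against 15, or 46.3-fold (27.8 to 83.2), the highest enrichment among the strongest 10 regions of this library. The 100 kb window with the most STAT5B excess reads was the same in both cytokine-treated STAT5B libraries, chromosome 19 from 29400001 to 29500000, with 24 regions after GM-CSF and 21 after both cytokines. On the same chromosome, the 100 kb from 29200001 to 29300000 ranked second among STAT3 windows after IL-21, with 9 regions.

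**Figure D1:**
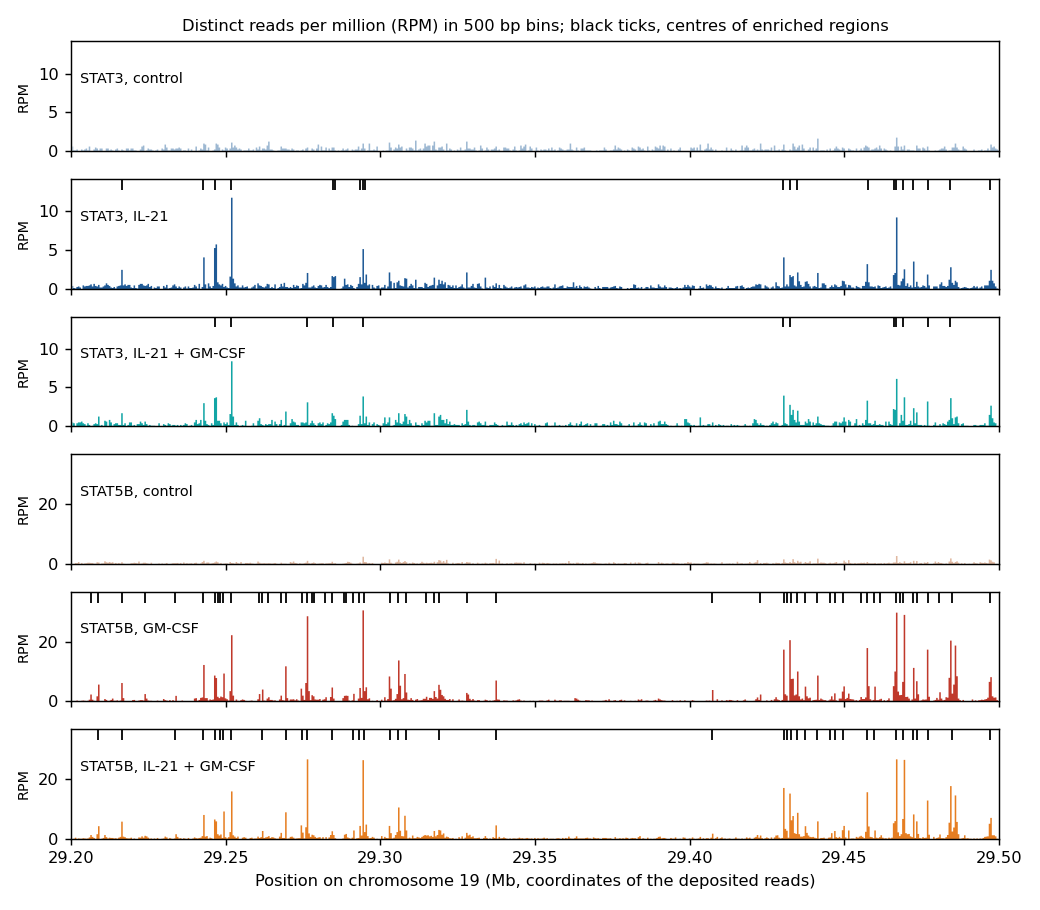
Reads per 1000000 distinct reads (RPM) in 500 bp bins (vertical axes, one scale per protein) over a 300 kb stretch of chromosome 19 (horizontal axis, Mb) in the 6 libraries, with black ticks at the centres of enriched regions. The highest bin reached 30.6 RPM for STAT5B after GM-CSF against 2.74 in its control, and 11.8 for STAT3 after IL-21 against 1.79 in its control.

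**Figure D2:**
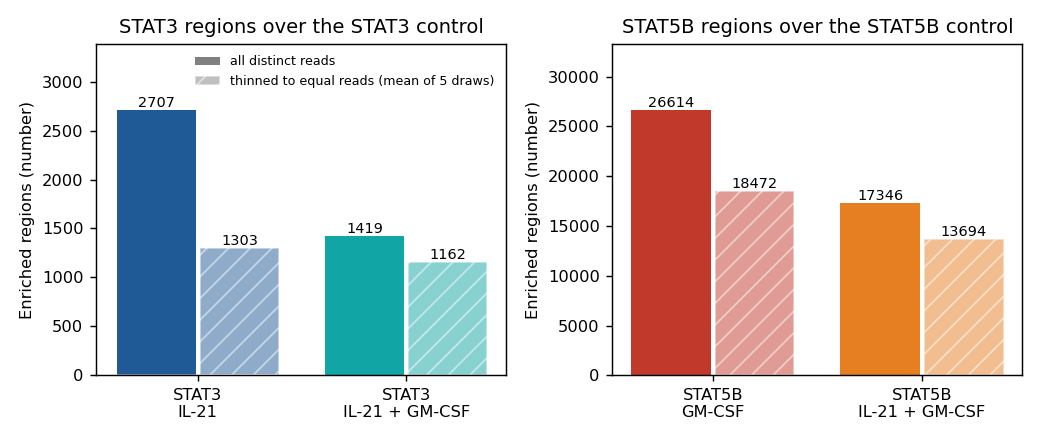
Number of enriched regions (vertical axes) in each cytokine-treated library over the control of the same antibody, with all distinct reads (solid bars) and with every library thinned at random to 7805341 distinct reads (hatched bars, mean of 5 draws). Thinning brought the STAT3 numbers to 1303 and 1162 and the STAT5B numbers to 18472 and 13694.

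Depth here means the number of distinct reads, and region numbers changed when it was made equal. Aligned reads were 25143231 (IL-21) and 25619850 (both cytokines) for STAT3, and 24062384 (GM-CSF) and 27622086 (both) for STAT5B. In each pair the library of both cytokines thus had more aligned reads but fewer distinct reads. Its lower depth went with more repeated reads and not with less sequencing. Region numbers after both cytokines were 0.524 times those after IL-21 for STAT3 and 0.652 times those after GM-CSF for STAT5B. With every library thinned to 7805341 distinct reads, these ratios were 0.888 to 0.897 for STAT3 and 0.736 to 0.743 for STAT5B over 5 draws. When repeated reads were kept, both orders turned, with 15792 STAT3 regions after IL-21 and 53700 after both cytokines, and 43238 STAT5B regions after GM-CSF and 56510 after both. In that setting exchanging the roles gave 78953 and 59441 regions for STAT3 and 26289 and 24811 for STAT5B.

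The next comparison asked how STAT3 binding after IL-21 differed when GM-CSF was added. Over the 3005 regions called in either library, pooled STAT3 reads, scaled to distinct reads, were 0.870 times as high with both cytokines as with IL-21 alone (0.861 to 0.878), and the median log2 ratio was -0.28. Of these regions 1119 were called in both libraries, 1588 with IL-21 only and 298 with both cytokines only, with median log2 ratios of -0.01, -0.65 and 1.21 in that order. The IL-21 library held more distinct reads than the library of both cytokines. By size, 298 regions were at least 2-fold lower with both cytokines and 182 at least 2-fold higher. With nearly equal reads per library, 1224 regions were called on a random 50% of reads and counted in the other 50%. Of these, 60 were lower and 31 higher. Counting chance around the pooled ratio there gave medians of 27 and 8 in 100 draws, and around equal levels 14.5 and 15. Among regions with at least 30 reads over the pair, the largest fall was on chromosome 3 at 18527201 to 18527400, from 35 reads to 2, a level 10.8-fold higher with IL-21 alone (2.79 to 93.1). Chromosome 1 at 155516201 to 155516400 went from 31 reads to 2, or 9.61-fold (2.44 to 82.8). In the other direction, chromosome 12 at 52769601 to 52769800 went from 8 reads to 32, 6.45-fold higher with both cytokines (2.91 to 16.2), and chromosome 2 at 75410401 to 75410800 from 30 to 64, or 3.44-fold (2.20 to 5.50). Among such regions, all 10 of the largest rises lay in STAT5B regions, and 9 of the 10 largest falls did, beside 84.4% of all 3005 regions. The direction depended on which regions were counted: over the regions called with both cytokines the median log2 ratio was 0.23. In the regions called and counted on separate parts of the reads it was -0.16, and thinning to equal reads alone gave -0.20.

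STAT5B binding with both cytokines was lower than in the library titled GM-CSF. Over 27901 regions the pooled ratio was 0.771 (0.769 to 0.772) and the median log2 ratio was -0.46, with 84.8% of regions below a ratio of 1. The median was -0.32 over the 15790 regions called in both libraries, -0.89 over the 10792 called with GM-CSF only and 0.82 over the 1319 called with both cytokines only. At least 2-fold lower levels were seen at 3488 regions and at least 2-fold higher levels at 297. In 16101 regions called and counted on separate parts of the reads, 922 were lower and 76 higher, against chance medians of 603 and 38 around the pooled ratio there (0.794). Counting chance around equal levels gave medians of 161 lower and 165 higher (135 to 203 higher over the draws). The 76 higher were thus more than chance around the pooled ratio gave and fewer than chance around equal levels gave. Among regions with at least 30 reads over the pair, the largest fall, on chromosome 10 at 77646001 to 77646400, was from 33 reads to 1, or 27.8-fold with a wide interval (4.66 to 1132). On chromosome 2 at 155429001 to 155429400 the reads went from 39 to 4, or 8.22-fold (2.97 to 31.7). The largest rise among them was on chromosome 4 at 46473801 to 46474200, from 7 reads to 25, or 4.23-fold (1.78 to 11.6). On chromosome 16 at 19874201 to 19874600 reads went from 11 to 37, or 3.99-fold (1.99 to 8.67), and this region was also a STAT3 region in both cytokine-treated STAT3 libraries. None of the 10 largest falls among them lay in a STAT3 region, and 3 of the 10 largest rises did, beside 8.90% of all 27901 regions. The median log2 ratio was -0.34 in the regions called and counted on separate parts of the reads and -0.44 after thinning to equal reads alone. It was -0.23 over the regions called with both cytokines. Whether the lower level belongs to the treatment or to this pair of libraries was not testable with 1 library per condition.

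**Figure D3:**
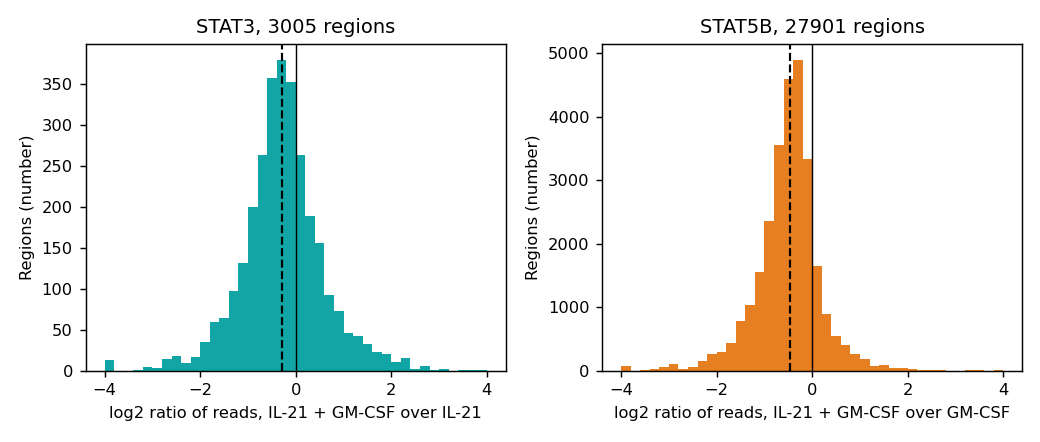
Number of regions (vertical axes) by log2 ratio of scaled distinct reads with both cytokines over the single cytokine (horizontal axes, values beyond 4 either way placed at the ends), for STAT3 at left and STAT5B at right. Dashed lines mark the medians of -0.28 and -0.46, and solid lines mark equal levels.

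The last comparison asked whether STAT3 and STAT5B bound the same places. Of the 2707 STAT3 regions after IL-21, 2222 (82.1%, Wilson interval 80.6 to 83.5%) overlapped a STAT5B region of the library titled GM-CSF by at least 1 bp. With both cytokines it was 1203 of 1419 (84.8%, 82.8 to 86.6%). Regions placed at random gave 0.488% and 0.317%, and regions placed at bins with the same number of control reads gave 18.7% and 16.5%. In reverse, 8.24% of STAT5B regions after GM-CSF overlapped a STAT3 region after IL-21, and 6.85% did with both cytokines. The set sizes keep these shares low, with 2707 STAT3 against 26614 STAT5B regions, and 1419 against 17346 with both cytokines. They do not show that STAT5B mostly bound apart from STAT3. Sharing rose with strength: 97.4% of the strongest 20% of STAT3 regions after IL-21 overlapped STAT5B against 65.1% of the weakest 20%, and for STAT5B after GM-CSF the shares were 27.9% and 0.883%. Strength was the reads summed over a region, and it was not separated from width. In the unions, shared regions were wider on average, at 265 against 213 bp for STAT3 and 559 against 319 bp for STAT5B. When an overlap had to cover at least 50% of both regions, 55.0% and 55.7% of STAT3 regions still qualified.

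At the 2537 STAT3 regions that overlapped STAT5B, STAT3 reads were 6.40 times control after IL-21 and 5.63 times with both cytokines, while STAT5B reads were 11.3 times control after GM-CSF and 9.66 times with both. At the 468 STAT3 regions without a STAT5B region, STAT3 reads were 8.74 and 6.68 times control. Their level was lower there, at 6742 RPM per Mb after IL-21 against 10433 at the shared regions, and so was the control, at 772 against 1630. STAT5B reads there were still 2.01 and 2.00 times control (intervals 1.91 to 2.11 and 1.91 to 2.11), although these regions were chosen for having no STAT5B call. At the 25419 STAT5B regions without a STAT3 region, STAT3 reads were 1.42 times control after IL-21 (1.41 to 1.43) and 1.56 times with both cytokines (1.55 to 1.57).

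**Figure D4:**
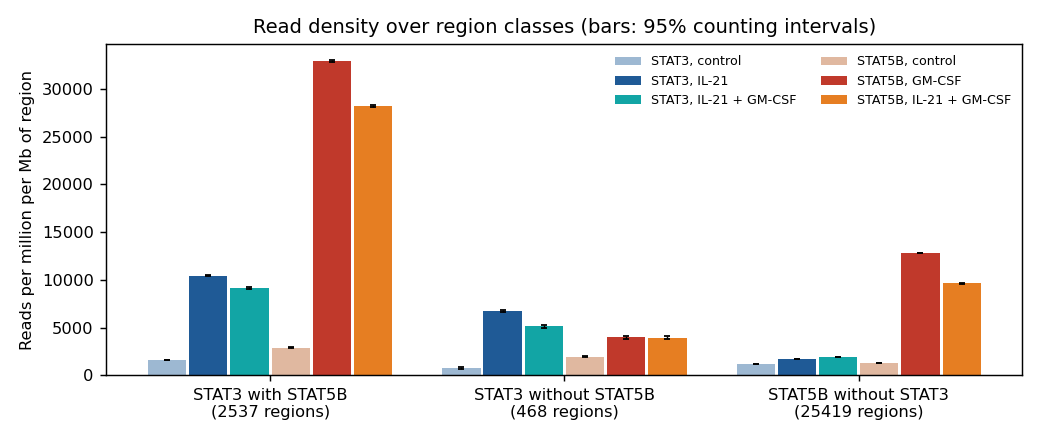
RPM per Mb of region (vertical axis) for the 6 libraries over 3 classes of regions (horizontal axis), with 95% counting intervals. STAT5B after GM-CSF stood at 32938 against 2922 in its control at STAT3 regions that overlap STAT5B, and at 12844 against 1272 at STAT5B regions without STAT3, or 11.3 and 10.1 times control.

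**Figure D5:**
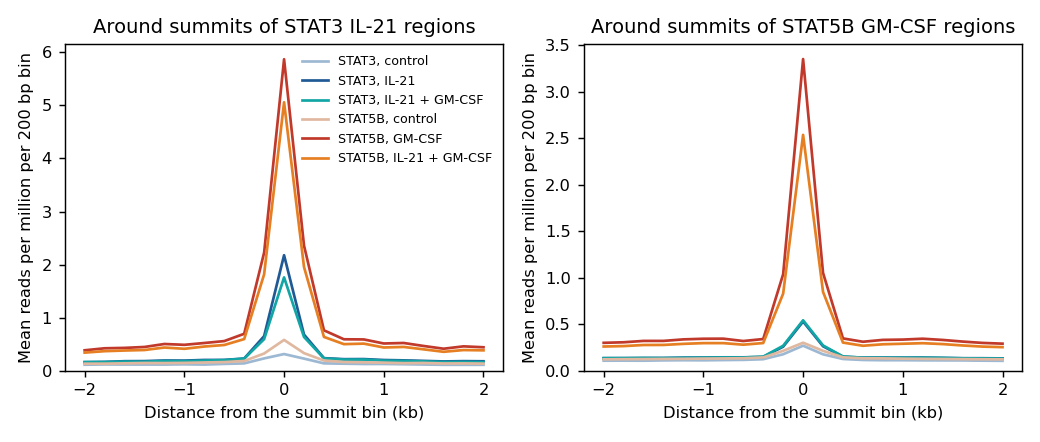
Mean RPM per 200 bp bin (vertical axes) by distance in kb from the summit bin (horizontal axes), around STAT3 regions of the IL-21 library at left and STAT5B regions of the GM-CSF library at right. At STAT3 summits the mean was 2.18 for STAT3 after IL-21 and 5.87 for STAT5B after GM-CSF, against 0.315 and 0.582 in their controls.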

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

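The score filter, the comparisons of co-treatment after thinning, on separate parts of 50% of the reads and after correction for filled start positions, and the placements matched on control reads were chosen after the data were examined. Of 100 alternative values, 51 stayed within the main value's interval or 1.5 times its count, 48 moved and 1 reversed; the cause was not tested except where named. With a q of at most 1e-06 there were 1668 STAT3 regions after IL-21 and 749 after both cytokines, and with at least 20 reads 782 after both. With repeated reads kept there were 15792 and 53700 STAT3 regions and 43238 and 56510 STAT5B regions, which turned the order of both pairs, and thinning left 1305 STAT3 regions after IL-21. The STAT3 median log2 ratio was -0.23 with background scaling, -0.35 with control reads subtracted, -0.44 with repeated reads, -0.37 over IL-21 regions, -0.20 after thinning, -0.16 on separate parts and -0.34 after correction for filled positions. It reversed to 0.23 over the regions called with both cytokines, where choosing regions by 1 library favours that library by construction. STAT3 regions at least 2-fold lower numbered 644 with control reads subtracted, 695 with repeated reads, 7 over co-treatment regions, 181 after thinning and 60 on separate parts, and those higher numbered 18 over IL-21 regions and 31 on separate parts. The STAT5B median was -0.53 with background scaling and -0.53 with control reads subtracted, -0.56 with repeated reads, -0.49 over GM-CSF regions, -0.23 over co-treatment regions, -0.44 after thinning, -0.34 on separate parts and -0.48 after correction. STAT5B regions lower numbered 6878 with control reads subtracted, 6375 with repeated reads, 368 over co-treatment regions, 5963 at 1.5-fold, 2281 after thinning and 922 on separate parts. Those higher numbered 708, 600, 15 over GM-CSF regions, 190 after thinning and 76 on separate parts. The overlap of STAT3 with STAT5B was 55.0% (IL-21 with GM-CSF) and 55.7% (both cytokines) with a minimum of 50% of both regions, 71.8% and 76.5% at 4-fold, and 81.3% with both cytokines after thinning. Depth limits weak sites most: the STAT3 control had the fewest distinct reads, and 5-fold sites were mostly missed in simulations.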

Other observations

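Tests chosen after the results were seen are the comparisons over 5 classes of STAT5B reads, the ratio of STAT5B reads with and without cytokine at STAT3 regions, the proportion of STAT3 to STAT5B reads, the STAT3 reads without GM-CSF at shared regions, and the comparison of overlap with regions of like reads; the other tests of explanations had their bounds written before their values were seen, though after the files were first read. The first tests of a common precipitation factor and of open chromatin left both undecided. Their written bounds were for a time replaced by those of later tests, chosen once the values were known, and were then restored word for word. The bound of the test over 5 classes was reworded after both of its STAT5B values were known.

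Sharing between the proteins went with the direction of the difference, also beside other regions with like summed reads. STAT5B regions overlapped 71.8% of the 298 STAT3 regions that stood lower with both cytokines (Wilson interval 66.5 to 76.6%), against 79.0% of other STAT3 regions with like reads, and 84.6% of the 182 that stood higher (78.7 to 89.1%), against 76.5%. Over all 3005 STAT3 regions it was 84.4%. STAT3 regions overlapped 66 of the 3488 STAT5B regions that stood lower (1.89%, 1.49 to 2.40%), against 3.28% of others with like reads, and 17 of the 297 that stood higher (5.72%, 3.60 to 8.97%), against 1.34%. Over all 27901 STAT5B regions it was 8.90%, above both. The lower and higher STAT5B regions had medians of 31 and 21 reads summed over the pair, against 52 over all. These regions were chosen and counted on the same reads.

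Chromosome X carried few regions of either protein: 0.309 STAT3 regions per covered Mb after IL-21 and 4.75 STAT5B regions after GM-CSF, against 1.40 and 11.9 on chromosome 1. Chromosome X had 0.293 to 0.333 times as many distinct reads as chromosome 1, and Y reads were present in every library. STAT3 regions on X numbered 33 after IL-21 and 6 with both cytokines, and the pooled ratio was 0.653 (0.578 to 0.736) over 34 X regions and 0.871 (0.863 to 0.880) on the autosomes. Of those X regions 33 were called in the IL-21 library, a choice of regions that favours that library.

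Fewer STAT3 regions were called with both cytokines than with IL-21. Thinned to equal reads the ratio of region numbers was at most 0.897, between the bounds set for depth as the cause (above 0.9) and against it (below 0.8), so depth may account for most of the gap and is not excluded. The lower ratio predicted for STAT5B taking STAT3's places was not seen. The median STAT3 log2 ratio was 0.27 higher in the third of regions with the most STAT5B (bootstrap interval 0.20 to 0.34). This sign does not decide the question. The STAT3 antibody pulling down STAT5B, or chromatin opened by cytokine, both left open below, could raise STAT3 reads at the same regions. A single weaker precipitation factor stays open: in the first test 3.28% of regions with at least 30 reads were 2-fold higher, within the 5% allowed, but 16.7% of intervals left out the pooled ratio, over the 10% allowed. The later comparison of the strongest and weakest 20% by STAT5B reads gave a difference of 0.17 (0.01 to 0.34), or 0.20 with filled positions corrected at the depth of the parts counted, and does not decide it either.

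Fewer STAT5B regions were called with both cytokines than in the library titled GM-CSF. Depth is argued against as the whole cause, since the ratio after thinning was at most 0.743. The lower ratio predicted for STAT3 taking the places was not seen. Regions with STAT3 stood 0.078 higher in log2 ratio than matched regions without (bootstrap interval 0.061 to 0.10). Chromatin opened by cytokine was not tested and could raise STAT5B reads there, so this sign does not decide the question. A single weaker precipitation factor cannot be told apart from a treatment effect: in the first test 0.333% of regions were 2-fold higher, as that factor needs, but 11.2% of intervals left out the pooled ratio, just over the 10% allowed. The later test over 5 classes first gave 0.11 (0.08 to 0.15), and 0.039 (0.0032 to 0.074) once filled positions were corrected at full depth, a correction made after the first value was seen, so the smaller value is not taken as deciding. An effect of IL-21 on STAT5B binding, and the conflicting label of the GM-CSF library, stay open as untested.

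Most STAT3 regions overlapped STAT5B regions, and open chromatin that any antibody pulls down was undecided by the first test, in which placement at bins of equal control reads gave 22.3% of the observed overlap, between the bounds of 10% and 50%. The narrower case of chromatin pulled down alike with and without cytokine is argued against, since STAT5B reads at all STAT3 regions were 10.4 times control (10.3 to 10.6), though chromatin opened by cytokine was not tested. The STAT3 antibody pulling down STAT5B may contribute and is not excluded: at the strongest 1000 STAT5B regions STAT3 reads were 1.04 times as high when GM-CSF was added (1.03 to 1.06), with a Spearman's rho across regions of 0.387, under the 0.5 set. As the whole source, STAT5B induced by GM-CSF is argued against. STAT3 reads without GM-CSF were already 6.79 times control (6.58 to 7.01) at the 1203 shared regions called with both cytokines. Those regions were called over the same STAT3 control, a choice that favours low control reads and can raise this ratio. At the strongest 1000 STAT5B regions, chosen without STAT3 reads, it was 2.73 times (2.68 to 2.79). STAT5B induced by IL-21 was not measured and stays open. STAT5B of any origin as the whole source was not decided, since 17.8% of those 1000 lay at least 2-fold from proportion, under the 20% set, though 48.1% lay outside the counting range and rho of STAT3 reads after IL-21 with STAT5B was 0.205.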
